A study of Mus musculus with 4 samples.

How the data were processed

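Single-nucleus RNA sequencing of microdissected mouse VTA was analysed in 4 libraries: a YFP control, an LH input, an NAc input and a PFC input. Per the labels' protocols, mice recovered for at least 3 weeks after virus injection and fibre implantation, the VTA was taken from 500 µm sections, inhibitors of transcription and translation (actinomycin-D and anisomycin) were in the buffers, and tissue of 3 to 4 mice per group was pooled. The target per library was 10000 nuclei and 350000000 reads. The deposited values are raw UMI counts per gene and barcode that the authors made with Cell Ranger 3.1.0 against mm10, per the file headers and the submitters' processing notes. Whether intronic reads were counted, and which annotation release was used, are not given in the sources used here. The files list 31053 genes and all 6794880 possible barcodes, with no cell calls and no cell-type labels. The opsin and YFP transgenes are not among these genes and were not analysed here.

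Barcodes were kept with at least 1000 detected genes and under 5% mitochondrial UMIs. The planned minimum was 500 genes, with 1000 as its alternative. They changed places after the barcode totals had been seen: 10106 control barcodes passed 500 genes, but 49681, 68181 and 44160 passed it in the LH-, NAc- and PFC-input libraries, far above the 10000 nuclei targeted and within the plateau of empty droplets. At 1000 genes 7850, 11541, 7320 and 16119 passed. With the change the dopaminergic-like core ratios were larger, and the 500-gene values stand beside them. Nuclei were clustered and named again for the 500-gene set, so its classes need not hold the same nuclei. The mitochondrial filter left 7712, 11420, 7151 and 16004 barcodes in the order control, LH, NAc and PFC. Scrublet, as in scanpy 1.11.5, was run per library with an expected rate of 0.08 and its own threshold, and removed 396, 648, 258 and 1086 barcodes (5.13%, 5.67%, 3.61% and 6.79%). Barcodes ranked beyond 20000 with at least 200 UMIs and under 1000 genes were taken as empty droplets: 53223, 69043, 64752 and 67149, with median UMIs of 402, 609, 660 and 570. Barcodes with at least 1000 genes, before the mitochondrial filter, held 65.9%, 57.0%, 53.0% and 65.1% of all UMIs.

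Counts were scaled to 10000 per nucleus and log-transformed. The 3000 most variable genes, without activity, heat shock and mitochondrial genes, gave 30 principal components over all libraries with no integration. A graph of 15 neighbours was clustered with the Leiden algorithm at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9), and the neurons were clustered again in the same way. Other tools were anndata 0.12.19, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15. Gene positions came from a GENCODE mouse annotation of the same build, which holds 99.6% of the genes in the files.

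Cell-type markers were fixed in advance, but the rules that turn them into names were set after the clusters had been seen, so differences from other annotations may come from rebuilt names. A cluster was named for the glial or vascular type with the highest mean log2 marker level over empty droplets, if that was at least 1 and no unrelated type reached 1, or neuronal above 0.3. Clusters of fewer than 20 nuclei, clusters with markers of both neurons and glia, and clusters with at least 3 genes of other immune cells among their 10 leading genes stayed unnamed. The immune gene set was added after the data had been seen. Among neurons, dopaminergic-like clusters had Slc6a3, Th and either Ddc or Slc18a2 at 2 times the median cluster or more, glutamatergic-like ones Slc17a6 at 80 CPM or more, and GABAergic-like ones Slc32a1 at 20 CPM or more with Gad1 or Gad2 at 100 CPM or more. Clusters that passed both of the last rules formed the glutamatergic-and-GABAergic-like class. The dopaminergic rule came before the glutamatergic one. Clusters 3 and 26 were thus named dopaminergic-like with Slc17a6 at 107 and 84.4 CPM, so these 2 classes are not separate in that marker. A neuronal cluster lost its name when more of its 10 leading genes were markers of another type than of its own. This left cluster 5 (Slc17a6 at 285 CPM), cluster 24 and cluster 45 unnamed, and an added alternative put them back in the glutamatergic-like, glutamatergic-and-GABAergic-like and GABAergic-like classes. Serotonergic, cholinergic, histaminergic and ependymal markers gave no class, and a cluster of 59 neurons led by Tph2 and Slc6a4 stayed unnamed. All neurons means every named or unnamed neuronal cluster not mixed with glia.

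UMIs were summed per library and class and divided by all UMIs of that class. Ratios were taken to the control library, with an exact conditional binomial interval, and sums and shares got exact Poisson and Clopper-Pearson intervals, all at 95%. With 1 library per group no test across samples was possible and none was made from cells. A gene with fewer than 3 UMIs in a library was set to a floor of 3 UMIs there for ranking and list medians, and ratios printed with an interval from 1 to 3 UMIs are the raw ones. For shares of nuclei with a UMI each nucleus was thinned to 1000 UMIs at random. A neuronal cluster was compared where both libraries had at least 50 nuclei. Free RNA was estimated per class and library from genes of other cell types and their level in empty droplets. The CPM that it would bring was its share times the CPM in empty droplets, a step added after the results had been seen, as were the comparison of the genes lower in control neurons with microglia-like nuclei and the median over pairs with a parent 8-fold apart.

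Genes were named by a rule fixed in advance: in all neurons and the dopaminergic-, glutamatergic- and GABAergic-like classes, core genes with at least 20 UMIs in both libraries together, members of the other lists with that depth and a ratio of at least 2 or at most 0.5, and in all neurons the 10 highest and 5 lowest ratios among genes with at least 100 UMIs in the higher library. In other classes core genes at those ratios were named. A gene with few control UMIs reaches 20 only where it is high in the other library. Counts of measured genes at 2 or more are therefore not like for like between inputs. The text names a part of the genes that qualify. The fixed lists were core rapid immediate-early (14 genes), extended rapid immediate-early (30, of which 29 are in the files, and which contains the core list), delayed activity-regulated (14), MAPK feedback (8), cAMP-CREB targets (8), heat shock (10), glucocorticoid response (10), interferon response (13), glial reactivity (12), dopamine synthesis and transport (11), neuropeptides (15), GABA-A receptor subunits (14) and ionotropic glutamate receptor subunits (17). Each list's median ratio was placed among 10000 random lists matched in 20 bins of expression.

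The ratio, interval and percentile steps were tested on simulated data with the depths of the real libraries and 50 genes at each known fold. Median estimates for a true fold of 2 were 1.98, 2.01 and 1.99 in the LH, NAc and PFC settings, and for a true fold of 4 they were 3.98, 3.99 and 3.98. Intervals held the true fold for 94% to 98% of these genes, and for 95.6%, 95.7% and 95.9% of unchanged genes. A list of 14 doubled genes stood at percentile 100 in each setting, and a list of 14 unchanged genes at 7.75, 16.0 and 43.4. These counts were simulated without differences between animals or between nuclei. Scaling by the median of ratios over expressed genes shifted the ratios by at most 0.10 in log2 units, in GABAergic-like nuclei with the NAc input.

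Alternatives numbered 21 set in advance and 5 added after the data had been seen. They covered the minimum number of genes, a UMI threshold per library (3144, 2921, 4058 and 2587 UMIs), a mitochondrial limit of 1%, no doublet removal, scaling within each library, Leiden resolution 2.0, activity genes kept for clustering, median-of-ratios scaling, free RNA subtraction, clusters weighted equally, the median over list members, other list members, a minimum of 50 UMIs per gene, thinning to 500 or 2000 UMIs or not at all, and other references. The added ones took the PFC-input library as reference, divided by the oligodendrocyte-like ratio, left out core genes that were 2-fold higher in empty droplets, left out of the totals genes that differed 8-fold in the control library alone, and named neuronal clusters without the rule on leading genes.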

Results

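The ventral tegmental area (VTA) is a midbrain nucleus that holds dopamine neurons together with glutamate and GABA neurons. The study asked whether light stimulation of axons that reach the VTA from different brain regions gives different immediate-early gene expression in VTA cell types. Immediate-early genes are transcribed within minutes of neuronal firing. Mice carried Cre-dependent channelrhodopsin-2 (ChR2), a light-gated cation channel, in GABA neurons of the lateral hypothalamus (LH input), in GABA neurons of the nucleus accumbens (NAc input) or in Slc17a7-expressing neurons of the prefrontal cortex (PFC input). Control mice carried yellow fluorescent protein (YFP) in GABA neurons of the LH. The PFC-input mice came from another Cre line (Vglut1-cre) than the other 3 groups (Vgat-cre), so for that input the line differs from the control together with the source of the axons. With the NAc input the line is that of the control, but the source of the axons differs. Only the LH input matches the control in both. Xist, the X-inactivation transcript, and Y-linked transcripts also differed between the pools, most from the control with the NAc and PFC inputs. For those inputs the mix of sexes cannot be told apart from the input either. All groups received 15 min of blue light at 20 Hz in 5 ms pulses over the VTA. Each group was 1 library of single nuclei from a pool of 3 to 4 mice aged 11 to 15 weeks, so there are no replicates and no difference was tested.

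Values are counts of unique molecular identifiers (UMIs, counted RNA molecules) summed over the nuclei of a class, given as CPM, that is, divided by all UMIs of the class and scaled to the same total. Brackets hold 95% intervals, Poisson or conditional binomial for sums and ratios and exact binomial for shares. These intervals cover counting error only, and not differences between pools of mice, dissections or library preparations. For sums and ratios each UMI was treated as independent, so variation between nuclei of a class is not covered either, and those intervals are too narrow where it is large. The libraries held 91531512 UMIs for the YFP control, 119033806 for the LH input, 116615763 for the NAc input and 125769058 for the PFC input. Nuclei with at least 1000 detected genes, under 5% mitochondrial UMIs and no doublet call numbered 7316 for the control, 10772 for the LH input, 6893 for the NAc input and 14918 for the PFC input. The minimum of 1000 genes replaced a planned minimum of 500 after the files had been read, and core ratios with 500 genes are given beside those of the neuronal classes.

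Neurons made up 47.9% (46.8 to 49.1) of the nuclei of the control library, 24.9% (24.1 to 25.7) with the LH input, 23.6% (22.6 to 24.6) with the NAc input and 17.2% (16.6 to 17.8) with the PFC input. Median depth per neuron was 10544.5 UMIs in the control, 10988 with the LH input, 16715 with the NAc input and 10584 with the PFC input. Dopaminergic-like clusters, named from markers such as Slc6a3 (the dopamine transporter) and Th (which makes the dopamine precursor), held 860, 511, 280 and 513 nuclei in that order. Glutamatergic-like clusters, marked by Slc17a6 (a vesicular glutamate transporter), held 1415, 1299, 876 and 1045. GABAergic-like clusters, marked by Slc32a1 (the vesicular GABA transporter) and Gad1 or Gad2 (which make GABA), held 398, 358, 189 and 478. Clusters with both sets of markers, named glutamatergic-and-GABAergic-like, held 576, 316, 176 and 333. Markers were read on UMIs summed per cluster, so this name does not show both sets in the same nucleus. Cluster 0, with 762 nuclei, had Slc17a6 at 89.5 CPM, near the limit of 80 CPM. The rules by which clusters were named were set after the data had been seen. They left 7.38% of the neurons of the control unnamed, 7.38% with the LH input, 6.40% with the NAc input and 7.42% with the PFC input. Neurons mixed with glia, also kept out of the classes, were 0.56% of nuclei in the control, 1.18% with the LH input, 0.464% with the NAc input and 1.18% with the PFC input.

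Microglia-like nuclei, from the resident immune cells of the brain, were 1.33% of the control library against 22.8% with the LH input, 19.1% with the NAc input and 33.5% with the PFC input. Oligodendrocyte-like nuclei, from the myelin-forming cells, were 30.0%, 25.6%, 20.6% and 18.6%. Oligodendrocyte precursor-like nuclei were 2.41%, 5.24%, 5.89% and 6.58%, and astrocyte-like nuclei 13.9%, 6.08%, 6.92% and 4.22%. Some clusters came almost wholly from 1 side of the comparison. Oligodendrocyte-like clusters 5 and 28 had 1727 of 1774 and 418 of 429 nuclei from the control, and astrocyte-like cluster 13 had 971 of 991. In the other 3 libraries oligodendrocyte-like nuclei came mainly from clusters 1, 3 and 7, and astrocyte-like nuclei from cluster 6. Leading genes were shared across this divide: Ptgds by clusters 1 and 5, Hapln2 and Carns1 by 3 and 28, and Slc6a11 and Itih3 by 6 and 13. Since no integration was made, a split of the same cell types by library cannot be told apart from separate populations. Microglia-like clusters 0, 15 and 17 had 7 of 4535, 0 of 974 and 4 of 924 nuclei from the control. Interferon-response genes led microglia-like cluster 25 and cell-division genes led microglia-like cluster 15. Unnamed clusters held 2.35% of nuclei in the control, 10.8% with the LH input, 20.1% with the NAc input and 14.5% with the PFC input.

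**Figure D1:**
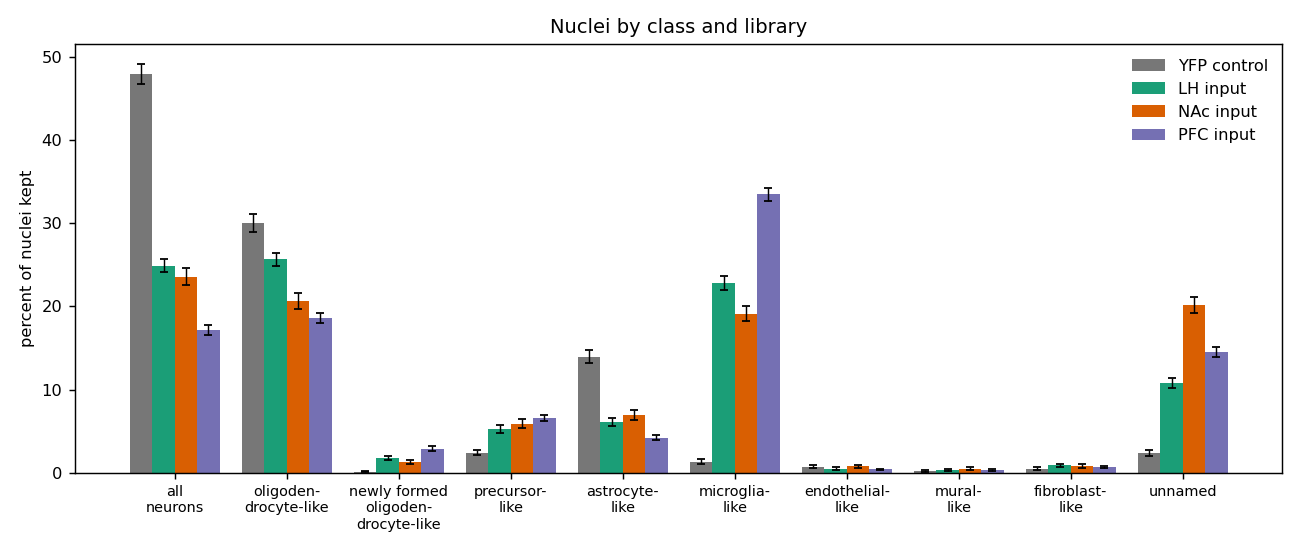
Percent of nuclei kept in each named class, by library, with exact binomial 95% intervals as error bars. Neurons were 47.9% of the control library and 17.2% to 24.9% of the other 3, and microglia-like nuclei 1.33% against 19.1% to 33.5%.

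The main measure was the summed CPM of 14 core rapid immediate-early genes chosen before the data were examined. They encode transcription factors of the Fos, Jun, Egr and Nr4a families and Npas4, the cytoskeletal protein Arc, the phosphatase Dusp1, and the early response proteins Ier2 and Btg2. In the mm10 genome Fos (ENSMUSG00000021250) lies on chromosome 12 at 85473890 to 85477273, Fosb (ENSMUSG00000003545) on chromosome 7 at 19302696 to 19310051 and Junb (ENSMUSG00000052837) on chromosome 8 at 84974484 to 84978718. Egr1 (ENSMUSG00000038418) lies on chromosome 18 at 34859823 to 34864984, Npas4 (ENSMUSG00000045903) on chromosome 19 at 4984355 to 4990316 and Arc (ENSMUSG00000022602) on chromosome 15 at 74669083 to 74672570. Nr4a1 (ENSMUSG00000023034) lies on chromosome 15 at 101254269 to 101274795 and Nr4a3 (ENSMUSG00000028341) on chromosome 4 at 48045153 to 48086447. Of the 14 genes, only Dusp1 overlaps another annotated gene on the same strand.

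The first comparison was the LH input against the control. Dopaminergic-like nuclei of the LH-input library had higher CPM of genes that mark recent activity than those of the control. Nr4a3, an orphan nuclear receptor, Fosb and Fos, subunits of the AP-1 transcription factor, and Fosl2, another AP-1 subunit, had the widest gaps among the measured genes of the fixed activity lists. Glutamatergic-like and GABAergic-like nuclei differed far less, and the glutamatergic-and-GABAergic-like nuclei differed by an amount that depended on the processing, at times more than the dopaminergic-like ones. Summed core CPM was 52.5 (48.4 to 56.8) in control and 207 (196 to 217) in LH-input dopaminergic-like nuclei, a ratio of 3.94 (3.58 to 4.33). Over all neurons it was 64.3 (61.9 to 66.8) against 120.4 (117 to 124), a ratio of 1.87 (1.78 to 1.97). The ratio was 1.25 (1.16 to 1.35) in glutamatergic-like nuclei, 1.17 (0.993 to 1.38) in GABAergic-like nuclei and 3.48 (2.99 to 4.07) in glutamatergic-and-GABAergic-like nuclei. With a minimum of 500 genes the ratios were 3.13 in dopaminergic-like nuclei, 1.76 over all neurons, 1.12 in glutamatergic-like, 1.36 in GABAergic-like and 2.54 in glutamatergic-and-GABAergic-like nuclei. In dopaminergic-like nuclei the ratio was 2.11 with the extended list and 3.20 without core genes higher in empty droplets. With cluster 5, which has Slc17a6 at 285 CPM but was left unnamed, the glutamatergic-like ratio was 1.10. After subtraction of free RNA the glutamatergic-and-GABAergic-like ratio was 9.11 (6.20 to 16.0) against 5.69 (4.95 to 6.60) in dopaminergic-like nuclei, and it was 6.74 with a mitochondrial limit of 1% and 6.06 at Leiden resolution 2.0. Divided by the ratio of the same libraries in oligodendrocyte-like nuclei the ratios were 2.53 in dopaminergic-like, 1.202 in all and 0.803 in glutamatergic-like nuclei, and against the mean of the other 3 libraries 1.26, 1.11 and 0.875.

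In dopaminergic-like nuclei 7 of 10 measured core genes had ratios of at least 2 with the LH input, and none was at or under 0.5. Nr4a3 was 3.47 CPM in the control and 49.6 with the LH input, 14.3-fold (10.3 to 20.4), or 7.93-fold with a minimum of 500 genes. Fosb was 0.434 against 7.13 CPM, 16.4-fold (6.61 to 52.8), and Fos 3.12 against 19.3 CPM, 6.19-fold (4.27 to 9.20). Egr1, a zinc-finger transcription factor, was 5.39-fold (3.65 to 8.16), or 3.48-fold with 500 genes, and Npas4, which regulates inhibitory synapses after calcium entry, 5.28-fold (3.83 to 7.40). Nr4a1 was 4.48-fold, Egr3 2.64-fold, Junb 1.98-fold and Btg2 1.54-fold. Among the extended rapid genes, of which 11 of 20 measured were at 2 or more, Fosl2 was 0.781 against 10.6 CPM, 13.5-fold (6.77 to 30.7), and Sik1, a kinase that limits CREB signalling, 4.43-fold. Per1, a clock gene with CREB sites, was 2.54-fold. Of the delayed activity-regulated genes, 1 of 13 measured was at 2 or more, Pcsk1, a prohormone convertase, with 70.4 against 167 CPM. Pim1, a kinase of the same list, was 0.412-fold (0.137 to 1.04). Of the MAPK feedback genes, the phosphatase Dusp4 was 2.40-fold and the receptor tyrosine kinase inhibitor Spry2 2.09-fold. The co-chaperone Dnajb1 was the heat shock gene at 2 or more, with 9.19 against 18.8 CPM. The neuropeptide gene Nts was 0.316-fold (0.0945 to 0.841).

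In glutamatergic-like nuclei 3 of 13 measured core genes were at 2 or more with the LH input: Nr4a3 at 2.03-fold, Egr3 at 2.46-fold and Fosb at 2.09-fold. Fos was 8.55 against 8.39 CPM. Atf3, a stress-responsive transcription factor, was 5.22-fold (2.28 to 13.96) and the phosphatase Dusp6 3.32-fold. The neuropeptide genes Cartpt and Penk were 0.466-fold and 0.401-fold. In GABAergic-like nuclei none of 8 measured core genes was at 2 or more. Egr1 was 1.80-fold (1.14 to 2.89) there, Npas4 0.665-fold (0.384 to 1.13), and the neuropeptide gene Sst 0.290-fold. In glutamatergic-and-GABAergic-like nuclei Nr4a3 was 2.70 against 29.5 CPM, 10.9-fold (6.42 to 19.8), Fos 5.00-fold (3.11 to 8.32) and Junb 3.43-fold. Those 3 genes were chosen after their values were seen.

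The second comparison was the NAc input against the control. Dopaminergic-like nuclei of this library had the highest core CPM of any neuronal class in any library, and 13 of 13 measured core genes were at 2 or more. Fosb and Egr4 had so few control UMIs that they counted as measured only through their level in this library. Fosb, Egr4, Nr4a3 and Egr1 led, and Homer1, a postsynaptic scaffold gene with an activity-dependent short form, was higher as well. Glutamatergic-like nuclei were higher to a smaller degree, and so were several glial classes of the same library. Oligodendrocyte precursor-like nuclei were an exception, with a ratio of 5.99 (4.46 to 8.23) that overlaps the dopaminergic-like one. Summed core CPM in dopaminergic-like nuclei was 365 (350.1 to 381), a ratio of 6.96 (6.36 to 7.63) to the control. Over all neurons it was 175 (171 to 180), a ratio of 2.73 (2.60 to 2.86). The ratio was 1.91 (1.78 to 2.05) in glutamatergic-like nuclei, 1.62 (1.39 to 1.90) in GABAergic-like nuclei and 2.18 (1.83 to 2.60) in glutamatergic-and-GABAergic-like nuclei. With a minimum of 500 genes the ratios were 5.59 in dopaminergic-like nuclei, 2.55 over all neurons, 1.77 in glutamatergic-like, 1.67 in GABAergic-like and 0.699 in glutamatergic-and-GABAergic-like nuclei. The dopaminergic-like ratio was 3.22 with the extended list and 3.81 without core genes higher in empty droplets. Divided by the oligodendrocyte-like ratio they were 3.34 in dopaminergic-like, 1.31 in all, 0.915 in glutamatergic-like and 0.779 in GABAergic-like nuclei, and after subtraction of free RNA the GABAergic-like ratio was 0.821 and the glutamatergic-and-GABAergic-like one 0.843, against 4.80 with a mitochondrial limit of 1%.

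In dopaminergic-like nuclei with the NAc input Fosb was 33.4 CPM, 77.1-fold (32.5 to 239.9), from 5 control UMIs. Nr4a3 was 67.3 CPM, 19.4-fold (14.002 to 27.6), Egr1 39.5 CPM, 13.4-fold (9.32 to 19.8), or 10.1-fold and 9.04-fold with a minimum of 500 genes, and Fos 33.2 CPM, 10.6-fold (7.43 to 15.6). Npas4 was 41.0 CPM, 9.47-fold (6.96 to 13.1), and Nr4a1 60.0 CPM, 6.29-fold (5.07 to 7.87). Egr3 was 10.6-fold and Arc 5.87-fold (2.55 to 15.1). Egr4 was 5.94 CPM against 0.173 CPM from 2 control UMIs, 34.2-fold (8.79 to 294). Junb was 3.79-fold and Btg2 2.50-fold. Of the extended rapid genes 20 of 23 measured were at 2 or more and 1, Klf4, at 0.489-fold. Fosl2 was 22.6-fold (11.5 to 50.8), Sik1 6.21-fold, Per1 3.84-fold, Jun 2.28-fold, and Cyr61, a secreted matrix protein gene, 4.08-fold. Homer1 was 78.0 against 208 CPM. Of 13 measured delayed genes 3 were at 2 or more: Homer1, Pcsk1 at 2.14-fold and Tiparp, an ADP-ribosyltransferase gene, at 2.33-fold. Inhba, an activin subunit gene, was lower, with 15.1 against 5.43 CPM. Of the heat shock genes Dnajb1 was 3.89-fold, Hspa1a 2.61-fold and Hsph1 2.04-fold. Zbtb16, a glucocorticoid-induced transcription factor gene, was 2.20-fold. Among neuropeptide genes 5 of 11 measured were at 0.5 or less, with Cck at 0.494-fold, Vip at 0.326-fold and Sst at 0.457-fold.

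In glutamatergic-like nuclei with the NAc input 5 of 13 measured core genes were at 2 or more. Nr4a3 was 3.65-fold (2.98 to 4.51), Fosb 4.61-fold (2.74 to 8.16), Egr1 2.21-fold, Nr4a1 2.06-fold and Egr3 2.03-fold. Fos was 8.55 against 14.4 CPM. Fosl2 was 3.02-fold, Sik1 2.02-fold and Per1 2.17-fold. Tac1 and Cck, neuropeptide genes, were 0.399-fold and 0.377-fold. In GABAergic-like nuclei Egr1 was 2.56-fold (1.64 to 4.06), the 1 core gene of 8 measured at 2 or more, and Nr4a3 was 0.974-fold (0.589 to 1.59). Cck was 0.149-fold and Inhba 0.489-fold there.

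The third comparison was the PFC input against the control. Here the dopaminergic-like ratio was close to the glutamatergic-like one and below the glutamatergic-and-GABAergic-like one. It was above the GABAergic-like one with overlapping intervals, and with a minimum of 500 genes it was the highest of these classes. Nr4a3 and Fosl2 had the clearest higher values in dopaminergic-like nuclei. Nr4a3 was also the leading core gene in glutamatergic-like nuclei, where Fos was close to the control. Th, the dopamine synthesis gene, was lower in dopaminergic-like nuclei. Summed core CPM in dopaminergic-like nuclei was 73.4 (67.2 to 80.1), a ratio of 1.40 (1.24 to 1.58). Over all neurons it was 84.7 (81.4 to 88.1), a ratio of 1.32 (1.25 to 1.39). The ratio was 1.38 (1.27 to 1.50) in glutamatergic-like nuclei, 1.13 (0.968 to 1.32) in GABAergic-like nuclei and 1.61 (1.34 to 1.93) in glutamatergic-and-GABAergic-like nuclei. With a minimum of 500 genes these ratios were 1.38 in dopaminergic-like nuclei, 1.23 over all neurons, 1.31 in glutamatergic-like, 1.18 in GABAergic-like and 0.545 in glutamatergic-and-GABAergic-like nuclei, where a mitochondrial limit of 1% gave 2.61. Divided by the oligodendrocyte-like ratio they were 0.902 in dopaminergic-like, 0.849 in all and 0.889 in glutamatergic-like nuclei, and against the mean of the other 3 libraries 0.353, 0.706 and 0.994.

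In dopaminergic-like nuclei with the PFC input 2 of 9 measured core genes were at 2 or more, Nr4a3 with 10.5 CPM, 3.02-fold (2.03 to 4.56), and Ier2 at 2.39-fold (0.946 to 6.34). Fos was 4.88 CPM, 1.56-fold (0.9498 to 2.57), Egr1 1.85-fold (1.13 to 3.03), Npas4 1.62-fold (1.07 to 2.46) and Nr4a1 1.82-fold (1.40 to 2.38). Btg2 was 0.765-fold (0.5998 to 0.971). Fosl2 was 3.50-fold, Sik1 2.02-fold, Dusp6 3.11-fold, Dusp4 2.15-fold and the chromatin remodelling gene Baz1a 2.07-fold. Hspa1a was 3.18-fold. Th was 190.5 against 89.9 CPM, 0.472-fold (0.431 to 0.516), and Tac1 0.316-fold. In glutamatergic-like nuclei 3 of 12 measured core genes were at 2 or more, with Nr4a3 at 2.90-fold (2.32 to 3.64), Fosb at 2.16-fold and Arc at 2.25-fold. Fos was 0.949-fold and Npas4 0.944-fold. Atf3 was 8.02-fold (3.55 to 21.2), Sik1 2.09-fold and Mt2, a metallothionein gene, 2.82-fold. In GABAergic-like nuclei none of 8 measured core genes was at 2 or more, and Th was 0.410-fold.

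**Figure D2:**
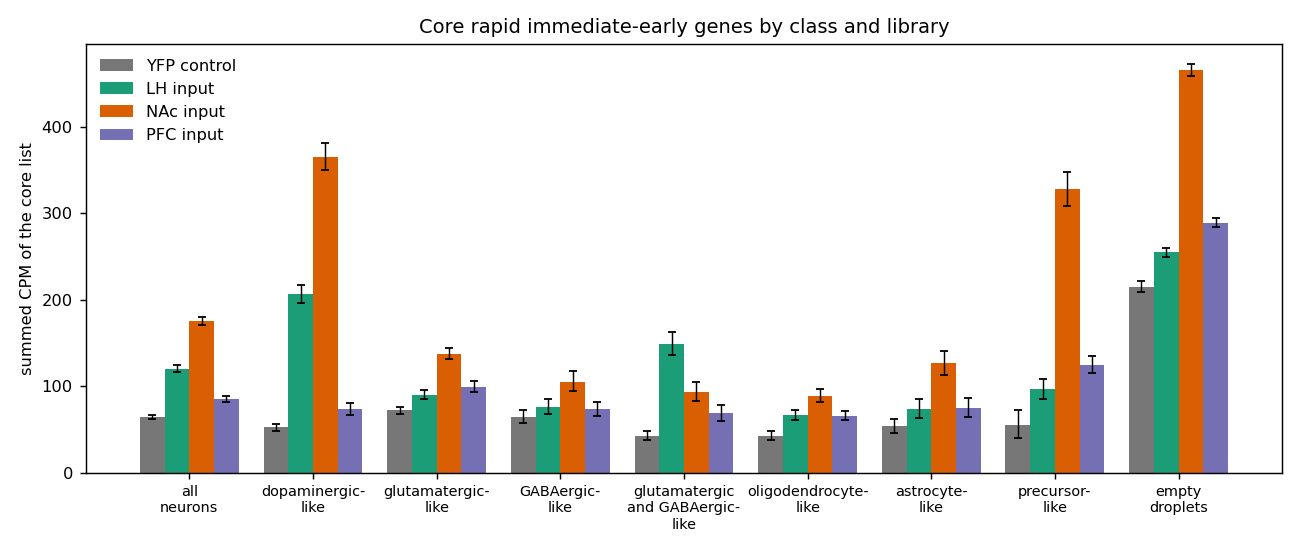
Summed CPM of the 14 core rapid immediate-early genes in each class and library, with Poisson 95% intervals. Dopaminergic-like nuclei stand at 52.5 CPM in the control, 207 with the LH input, 365 with the NAc input and 73.4 with the PFC input.

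**Figure D3:**
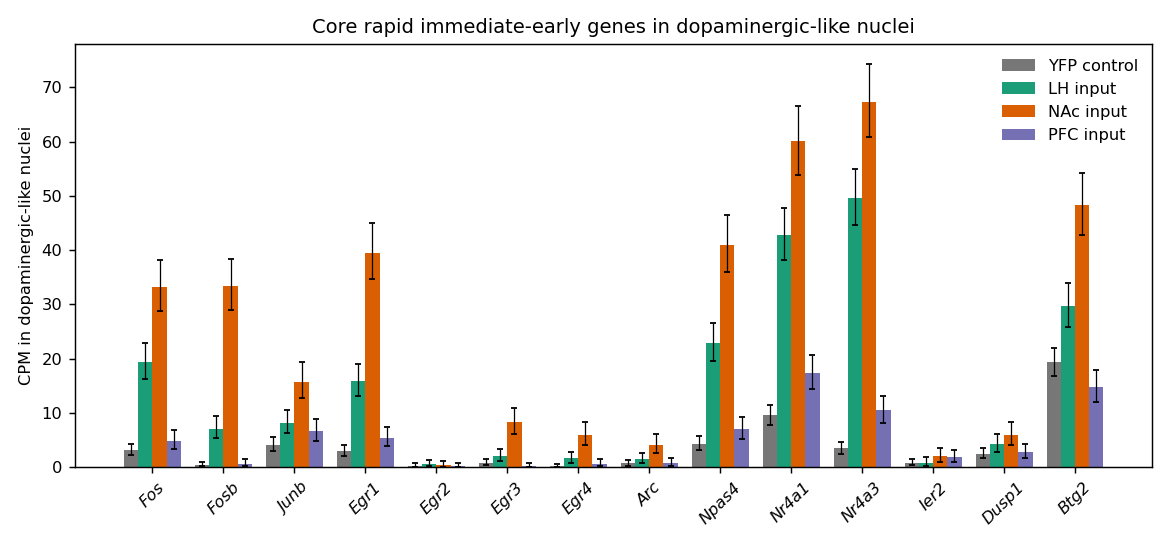
CPM of each of the 14 core genes in dopaminergic-like nuclei of the 4 libraries, with Poisson 95% intervals. Nr4a3 stands at 3.47 CPM in the control, 49.6 with the LH input, 67.3 with the NAc input and 10.5 with the PFC input.

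Inputs were also set against one another. In dopaminergic-like nuclei core CPM with the LH input was 2.81 (2.54 to 3.12) times that with the PFC input, and with the NAc input 4.98 (4.52 to 5.49) times. In glutamatergic-like nuclei these ratios were 0.907 and 1.38, and in GABAergic-like nuclei 1.03 and 1.44. Among dopaminergic-like clusters, cluster 4, rich in Slc6a3 and Chrna6 (a nicotinic receptor subunit), had ratios to the control of 8.82 (6.97 to 11.3) with the LH input, 17.0 (13.5 to 21.6) with the NAc input and 1.54 with the PFC input. Cluster 3, with Otx2os1 and Cck among its leading genes, had 3.20, 6.77 and 1.32. Cluster 8, with Drd2 among its leading genes, had 3.04, 5.37 and 1.48, and cluster 6, led by Aldh1a1, had 4.00 with the LH input and 1.37 with the PFC input. Cluster 4 was the largest dopaminergic-like cluster in the control (177 nuclei), cluster 3 with the LH input (135) and the PFC input (153), and cluster 8 with the NAc input (63). The glutamatergic-and-GABAergic-like excess with the LH input lay in cluster 7, at 9.86 (7.12 to 13.95), with 1.84 in cluster 0. Glutamatergic-like cluster 2, rich in Tac1, had 1.83 with the LH input, 3.99 (3.11 to 5.15) with the NAc input and 2.46 (1.75 to 3.46) with the PFC input. Glutamatergic-like cluster 13 had 3.09 and 5.71 with the LH and NAc inputs, and glutamatergic-like clusters 10 and 19 had 2.05 and 2.17 with the LH input. Unnamed neuronal cluster 24, with Gad2 at 596 CPM, had 5.73 (3.05 to 11.7) with the LH input, from 12 core UMIs in the control. Lower values than the control with the LH input were found in glutamatergic-like cluster 11, rich in Bdnf and Adcyap1, at 0.713 (0.604 to 0.842), and in unnamed neuronal cluster 5 at 0.371 (0.279 to 0.488).

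**Figure D4:**
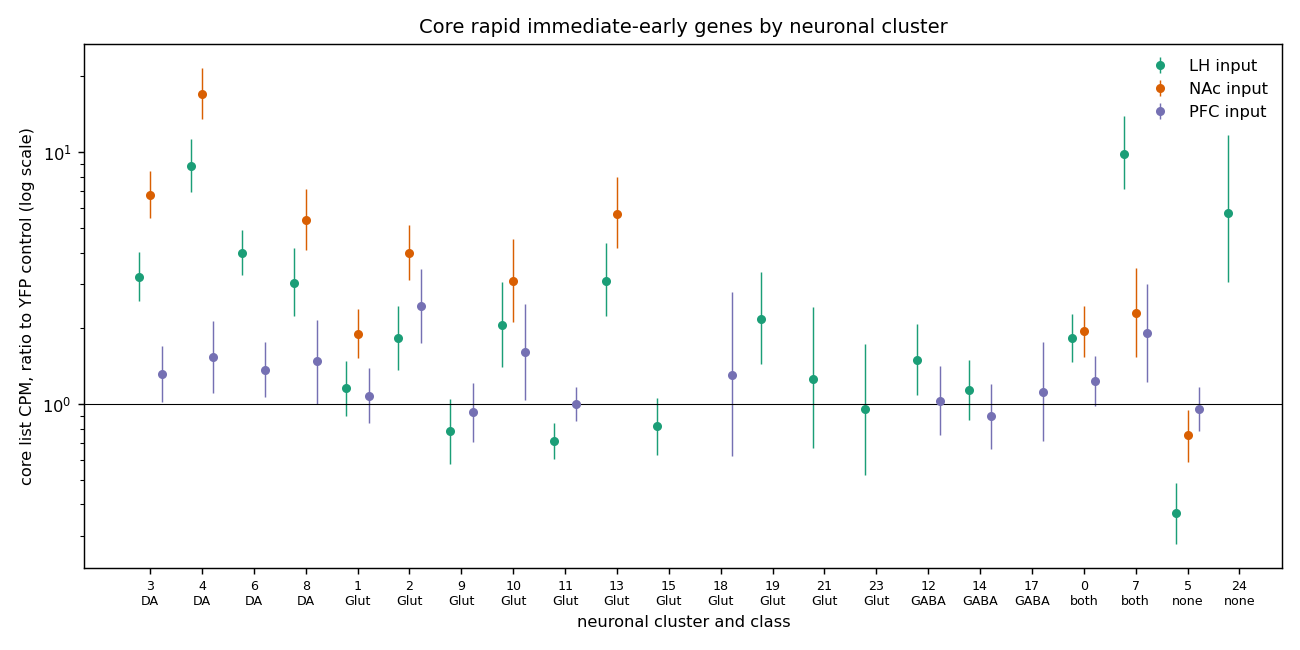
Ratio of core CPM to the control for each neuronal cluster with at least 50 nuclei in both libraries, on a log axis with 95% counting intervals. Dopaminergic-like cluster 4 stands at 8.82 with the LH input and 17.0 with the NAc input. Unnamed clusters 24 and 5 stand at 5.73 and 0.371 with the LH input.

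The share of nuclei with a Fos UMI was compared after thinning each nucleus to 1000 UMIs, which left out 0 nuclei. In dopaminergic-like nuclei it was 0.233% in the control, 2.54% (1.36 to 4.31) with the LH input, 4.29% (2.23 to 7.37) with the NAc input and 0.195% with the PFC input. The PFC-input share rests on 1 nucleus and lies above the control at other depths, at 0.585% against 0.233% for 500 UMIs and 1.56% against 0.465% for 2000 UMIs. In oligodendrocyte-like nuclei, used as the class where neuronal activity genes should be low, it was 0.273%, 0.760%, 2.04% (1.37 to 2.92) and 0.937%. With the NAc input it was also 4.40% in microglia-like, 3.94% in oligodendrocyte precursor-like and 3.56% in astrocyte-like nuclei, and the intervals of these glial shares overlap the dopaminergic-like one. Without thinning, the dopaminergic-like shares were 3.14%, 16.8%, 24.6% and 4.68% at median depths of 12435.5, 13325, 19016 and 12876 UMIs. The unthinned oligodendrocyte-like shares were 0.819%, 2.43%, 7.74% and 2.67% at 2563, 2728.5, 4013 and 2766 UMIs. The thinned dopaminergic-like Nr4a3 share was 0 of 860 nuclei in the control, 4.50% (2.87 to 6.68) with the LH input, 3.57% (1.73 to 6.47) with the NAc input and 0.585% with the PFC input, and the oligodendrocyte-like share at most 0.422% in any library. The thinned Nr4a1 share in dopaminergic-like nuclei was 0.814%, 4.70%, 6.43% and 1.95%, and the Npas4 share 0.814%, 2.54%, 2.86% and 0.390%.

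Immediate-early CPM outside neurons was higher than the control in several classes, above all with the NAc input, and lower or near it in others, and much of it was within what free RNA would bring. In oligodendrocyte precursor-like nuclei of that library, most of them from cluster 9 against cluster 22 in the control, core CPM was 328 against 54.7, a ratio of 5.99 (4.46 to 8.23) that overlaps the dopaminergic-like one. Fos there was 56.4 CPM against 1.19 CPM from 1 control UMI, 47.4-fold (8.40 to 1882), Egr1 9.12-fold (3.49 to 33.9) and Nr4a3 18.1-fold (6.12 to 88.5) from 3 control UMIs. Free RNA would bring 82.8 of the 328 CPM and 41.2 of the 54.7 CPM. In oligodendrocyte-like nuclei the core ratio was 1.56 (1.34 to 1.81) with the LH input, 2.09 (1.80 to 2.43) with the NAc input and 1.55 (1.34 to 1.80) with the PFC input. Core CPM there was 42.5, 66.2, 88.7 and 65.9 in the order control, LH, NAc and PFC. Free RNA would bring 33.9, 57.8, 79.5 and 61.2 CPM of it, so by this estimate nearly all of the difference lies within free RNA. The estimate runs too high in some classes, with free RNA at 110% of UMIs in endothelial-like nuclei with the NAc input. In mural-like nuclei with the PFC input it was 116%. It may be too high in other glial classes as well, so expression by their nuclei is not excluded. Fos in oligodendrocyte-like nuclei was 6.28-fold (3.90 to 10.6) and Junb 3.21-fold with the NAc input, with free RNA at 71.0% and 75.0% of these differences. In astrocyte-like nuclei the core ratio with the NAc input was 2.34 (1.95 to 2.82), with 68.3 of 126.5 CPM from free RNA, and Fos was 5.61-fold. In microglia-like nuclei the core ratio was 0.938 (0.657 to 1.39) with the LH input, 1.72 (1.205 to 2.53) with the NAc input and 0.786 (0.552 to 1.16) with the PFC input, and in fibroblast-like nuclei 0.211, 1.50 and 0.434. In barcodes without a nucleus, which hold free RNA, core CPM was 215 in the control, 255 with the LH input, 466 with the NAc input and 289 with the PFC input.

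Whole lists were placed among 10000 random lists of genes with matched expression, as a description and not a test. Over all neurons the median core-gene ratio was 1.72 with the LH input, 2.58 with the NAc input and 1.21 with the PFC input, at percentiles 100, 100 and 96.4. The extended rapid list had medians of 1.56, 2.22 and 1.28. The delayed activity-regulated list had medians of 1.23, 1.19 and 1.09 at percentiles 99.9, 97.6 and 78.1. MAPK feedback genes had medians of 1.28, 1.48 and 1.17, and cAMP-CREB targets 1.13, 1.33 and 1.01. Heat shock genes had medians of 1.21, 1.21 and 1.30, and glucocorticoid-response genes 0.982, 1.00 and 0.998. GABA-A receptor subunits had 0.936, 0.841 and 0.903, ionotropic glutamate receptor subunits 1.04, 1.09 and 1.02, and dopamine synthesis and transport genes 0.856, 0.812 and 0.892. In dopaminergic-like nuclei the core medians were 4.87, 9.47 and 1.62, and the extended medians 2.26, 4.08 and 1.56.

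Over all neurons the median of interferon-response and glial reactivity genes was higher than in the control with every input, and that of neuropeptide genes lower. Bst2 also differed in barcodes without a nucleus, where no list medians were taken. Interferon-response genes had medians of 2.16, 1.33 and 3.44 over all neurons. Bst2, which tethers budding virus, was 13.7-fold, 10.0-fold and 21.3-fold, and the antigen presentation genes B2m and H2-K1 4.07-fold and 5.48-fold with the LH input. Glial reactivity genes had medians of 3.27, 2.61 and 4.13. Spp1, secreted osteopontin, was 33.1 CPM in the control against 215, 218 and 214 CPM, Gfap, an astrocyte filament gene, 4.98-fold, 2.80-fold and 10.0-fold, and Cd68, a microglial lysosome gene, 5.87-fold, 3.55-fold and 7.40-fold. Free RNA was put at 12.8% of neuronal UMIs in the control and 14.2% to 14.5% in the other 3 libraries. Bst2 was 14.9, 117, 114 and 195 CPM in barcodes without a nucleus, so free RNA would bring 1.91, 16.9, 16.2 and 28.1 CPM, more than the 0.514, 7.05, 5.16 and 10.9 CPM found in neurons. It would also bring more than was found of B2m, H2-K1, Spp1, Gfap and Cd68 in every library, so these values give no evidence of expression by neurons, and the estimate of free RNA is too high for such genes. By the same estimate free RNA would cover the whole difference of Nts in dopaminergic-like nuclei with the LH input, of Cck and Sst with the NAc input, and of Fos, Dusp6, Baz1a, Hspa1a and Tac1 with the PFC input. It would do so in glutamatergic-like nuclei for Atf3, Dusp6 and Cartpt with the LH input, Fos and Cck with the NAc input and Atf3 with the PFC input, and in GABAergic-like nuclei for Cck with the NAc input and Th with the PFC input. For Fos, Fosb, Nr4a3 and Egr1 in dopaminergic-like nuclei with the LH and NAc inputs it would bring at most 25.8% of the difference. In oligodendrocyte-like nuclei the interferon medians were 5.89, 3.67 and 9.97 and the glial reactivity medians 4.51, 4.16 and 6.27. Neuropeptide genes had medians of 0.615, 0.442 and 0.799 over all neurons. Penk, which encodes enkephalins, was 20.0 against 9.54 CPM with the LH input, Cck 60.2 against 21.5 CPM and Npy 1.44 against 0.337 CPM with the NAc input, and Th 64.2 against 27.2 CPM with the PFC input. In oligodendrocyte-like nuclei, which are not known as a source of these peptides, neuropeptide medians were 0.641, 0.343 and 0.377.

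Most of the genes with the highest ratios over all neurons had no UMI in the control. Rpl13, a ribosomal protein gene, was at least 832-fold higher with the LH input, at least 434-fold with the NAc input and at least 896-fold with the PFC input, with the control set to the floor of 3 UMIs. Ate1, Tcf25, Cox4i1, Chchd2, Trf, Ndufa13, Ube2b and Oxsr1 were among the 10 highest with every input, as at least 619-fold for Ate1 and at least 338-fold for Trf with the LH input. The other members were Trappc2l at least 87.1-fold with the LH input, Afg3l1 at least 79.0-fold with the NAc input, and Ifi27l2a 70.2-fold (33.7 to 176) with the PFC input. The lowest were copies of ribosomal protein genes, such as Rpl9-ps6 at 0.00506-fold, 0.0041-fold and 0.00514-fold and Rpl27-ps3 at 0.0103-fold, 0.00607-fold and 0.00725-fold, and Rps12-ps3, Gm2000, Gm9493 and Gm10031. The levels of such genes are uncertain. The ribosomal copies share sequence with their parent genes, and all 10 genes with no UMI in the control and at least 1000 UMIs in each other library overlap another annotated gene on the same strand. At 8-fold or more with at least 100 UMIs, 28 genes were higher in control neurons than in each other library and 24 lower, against 0 and 0 for the LH input, 1 and 0 for the NAc input and 0 and 0 for the PFC input. Of the genes measured in empty barcodes, 27 of 27 higher and 22 of 23 lower ones differed there too. Of the 24 lower genes, Mpeg1, Laptm5, Fcrls, Bst2, Ctsc and Stab1 were at least 8-fold higher in microglia-like nuclei than in neurons with every input. Free RNA would cover their neuronal values, so these 6 can follow the scarcity of microglia-like nuclei in the control. It would also cover 12 of the other 18, so coverage alone does not set the 6 apart. Mpeg1 in microglia-like nuclei was 300 CPM in the control against 314, 353 and 500 CPM, so it was counted there. None was a core gene.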

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

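The tests of gene overlap on 1 strand and of microglial genes in the control were set before their results were seen, and all other tests named here only afterwards: free RNA, a control counted differently, a uniform difference across the library, reads given to a copy, lower expression in the control mice, the minimum number of genes, and virus, implant or dissection.

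Several results stood out because their direction differed between classes or clusters, and these differences were not tested. Core immediate-early CPM was lower than in the control in unnamed neuronal cluster 5, at a ratio of 0.371 with the LH input and 0.752 with the NAc input, and in glutamatergic-like cluster 11, at 0.713 with the LH input, while it was higher over all neurons. In fibroblast-like nuclei it was 0.211 of the control with the LH input and 0.434 with the PFC input, from 35 control nuclei. Nr4a3 there was 310 CPM in the control and 2.69 CPM with the LH input. Other signals lay in data outside the main measure. In barcodes without a nucleus the core ratio was 1.18 with the LH input, 2.17 with the NAc input and 1.34 with the PFC input. Unnamed clusters held 10.8% of nuclei with the LH input, 20.1% with the NAc input and 14.5% with the PFC input, against 2.35% in the control. Clusters led by genes of other immune cells, by haemoglobin genes and by the heat shock genes Hspa1a and Hspa1b were among them.

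The first pattern weighed was the higher core immediate-early CPM in dopaminergic-like nuclei with the LH and NAc inputs. The tables argue against free RNA, since the lower of the 2 ratios after subtraction was 5.69 (4.95 to 6.60), against 3.94 without it though the subtraction takes too much of some genes from neurons, and against a control that was counted differently, since over the PFC-input library, which lacks the control's gaps, the lower ratio was 2.81 (2.54 to 3.12). They also argue against a uniform difference across the library, with a lower quotient of the dopaminergic-like ratio over the highest of glutamatergic-, GABAergic-, oligodendrocyte- and astrocyte-like nuclei of 2.53, but those 4 classes were chosen with the values known, and 3 left out came close or passed it: mural-like nuclei at 4.59 (0.720 to 192) with the LH input and 5.44 (0.893 to 223) with the NAc input from 1 control UMI, oligodendrocyte precursor-like nuclei with the NAc input at 5.99 (4.46 to 8.23) and glutamatergic-and-GABAergic-like nuclei with the LH input at 3.48 (2.99 to 4.07), or 9.11 (6.20 to 16.0) after subtraction of free RNA, above the dopaminergic-like 5.69. In oligodendrocyte precursor-like nuclei free RNA would bring 82.8 of 328 CPM with the NAc input and 41.2 of 54.7 CPM in the control. Subtraction would therefore widen that ratio as well. A candidate explanation is a response to the stimulated inputs that is strong in dopamine neurons and not limited to them, which remains a hypothesis found and examined in the same 4 libraries. Differences between pools of mice, and handling before freezing, were not tested, since each group is 1 library.

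The second pattern was the set of genes absent or far lower in the control library than in each other library. All of the 10 genes with no UMI in the control and at least 1000 in each other library (100%) overlap another annotated gene on the same strand, against 0 to 80% in random sets matched for expression. This is consistent with reads lost to overlapping genes, as an annotation with other transcripts would give, and the count of 10 overlapping genes lay above the 0 to 8 of random sets, which argues against lower expression of these 10 in the control mice; both readings rest on the same evidence. For genes with a named copy, mostly of ribosomal proteins, parent plus copy differed by a median of 1.68-fold (1.37 to 4.69) over 10 pairs against 15.6-fold for the parent alone, but 4.39-fold in the 6 pairs with a parent 8-fold apart, and reads given to a near-identical copy cannot be told apart from other causes there, because the spread over so few pairs is wide and the prediction was reworded after its value was seen. To enter these pairs a copy had to be at least 8-fold higher in the control than in the mean of the others. The pairs were thus chosen on values that the test uses. No core gene was among the genes that were 8-fold apart, and these genes held 0.0445% of control neuron UMIs. Of the 24 lower in control neurons, 6 were at least 8-fold higher in microglia-like nuclei with every input and can follow free RNA of microglia, and neither test covers them.

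The third pattern was the scarcity of microglia-like nuclei in the control, 1.33% against 19.1% or more. The tables argue against the minimum number of genes as its source, since with 500 genes the share of microglia-like among named nuclei in the control was 0.0564 of the lowest other library. Microglial genes that were not counted in the control are argued against only for the microglia-like nuclei that were found. There the median marker level was 1.93 times that of the other libraries, though 85 of these 97 control nuclei lay in 1 cluster. The same markers named the class, so nuclei without their counts were unlikely to enter it, and the test cannot speak for them. The control also had a virus and light over the VTA, so the presence of a virus or an implant does not set it apart. The kind of virus, the extent of damage by implants, and dissection cannot be told apart. The control differs from all 3 others at once, by at least 14.4 times, and the design holds no second control library. Candidate explanations are a reaction of microglia to the opsin virus, less damage by implants in the control, and a control prepared in another way. None was tested.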

How the results depend on the processing

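The use of the PFC-input library as reference, the division by the oligodendrocyte-like ratio, the omission of core genes higher in empty droplets, the omission of genes 8-fold apart in the control and the naming of clusters by transmitter genes alone were chosen after the data had been seen, and the minimum of 1000 genes took the place of the planned 500 after the barcode totals had been seen. No paired analysis was possible because each group is 1 library and every library has replicate number 1 in the labels. Depth limits single genes most: dopaminergic-like nuclei with the NAc input numbered 280, and Egr4 had 2 UMIs in the control. Of 218 core ratios under an alternative, over all neurons and the dopaminergic-, glutamatergic- and GABAergic-like classes, 133 stayed within the counting interval, 73 moved outside it with the same direction or from a ratio whose interval held 1, and 12 reversed. A further 4 reversed in glutamatergic-and-GABAergic-like nuclei. In dopaminergic-like nuclei the ratio stayed above 1 under all 18 alternatives with the NAc input (3.22 to 10.04) and with the LH input (1.26 to 5.69). The number of core genes at 2 or more in all neurons stayed within 1.5 times in 9 of 9 settings. Of 126 values of single genes in dopaminergic-like nuclei 122 stayed within their interval, and the 4 others came with the 500-gene minimum: Egr1 at 3.48 and 9.04 and Nr4a3 at 7.93 and 10.1 with the LH and NAc inputs. Of 60 Fos shares at another depth or without thinning 41 moved. Such a share depends by construction on the UMIs kept per nucleus, so these moves do not measure stability. In dopaminergic-like nuclei with the LH input it was 0.783% at 500 UMIs, 2.54% at 1000, 3.72% at 2000 and 16.8% without thinning. Leaving out genes 8-fold apart in the control from the totals moved no ratio. By construction it could not, since these genes held at most 0.0492% of neuron UMIs in any library and no core gene was among them. It does not speak to how core genes were counted in the control.

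With at least 500 genes the core ratio over all neurons was 1.76 for LH, 2.55 for NAc and 1.23 for PFC, in dopaminergic-like nuclei 3.13 for LH and 5.59 for NAc, and in glutamatergic-like nuclei 1.12 for LH and 1.77 for NAc. In glutamatergic-and-GABAergic-like nuclei it reversed to 0.699 for NAc and 0.545 for PFC. Neurons were then 58.4% of named nuclei in the control, 27.0% for LH, 27.9% for NAc and 18.6% for PFC, against main values on the same base of 49.4%, 28.3%, 29.7% and 20.3%. Dopaminergic-like nuclei were 11.5%, 14.6%, 12.4% and 15.4% of neurons against 24.5%, 19.1%, 17.2% and 20.0%, and microglia-like nuclei 41.5% of named nuclei for PFC against 39.7%. Clustering and naming were repeated for this set, so its classes need not hold the same nuclei as the main ones. The cause was not tested.

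With free RNA subtracted the ratio over all neurons was 2.32 for LH, 3.02 for NAc and 1.196 for PFC, in dopaminergic-like nuclei 5.69 for LH and 10.04 for NAc, and in glutamatergic-like nuclei 1.69 for NAc. It was 0.924 for LH, 0.821 for NAc (reversed) and 0.809 for PFC in GABAergic-like nuclei, and 9.11 for LH and, reversed, 0.843 for NAc in glutamatergic-and-GABAergic-like nuclei. Subtraction removes by construction more where empty droplets hold more core UMIs, and it takes too much of genes such as Bst2 from neurons.

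Against the mean of the other 3 libraries, which by construction holds the other stimulated libraries, the ratio over all neurons was 1.11 for LH, 1.95 for NAc and, reversed, 0.706 for PFC. In dopaminergic-like nuclei it was 1.26, 3.30 and, reversed, 0.353. In glutamatergic-like nuclei it reversed to 0.875 for LH and 0.994 for PFC and was 1.58 for NAc. In GABAergic-like nuclei it was 0.934 for LH and 0.894 for PFC, and in glutamatergic-and-GABAergic-like nuclei it reversed to 0.724 for PFC. Against the PFC-input library it was 1.42 for LH and 2.07 for NAc over all neurons, 2.81 and 4.98 in dopaminergic-like nuclei, and 0.907 (reversed) and 1.38 in glutamatergic-like nuclei.

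The oligodendrocyte-like ratio is above 1 for every input and lies mostly within the estimate of free RNA. Divided by it, the ratio over all neurons was 1.202 for LH, 1.31 for NAc and, reversed, 0.849 for PFC. In dopaminergic-like nuclei it was 2.53, 3.34 and, reversed, 0.902. It reversed to 0.803, 0.915 and 0.889 in glutamatergic-like nuclei and was 0.751, 0.779 (reversed, for NAc) and 0.729 in GABAergic-like nuclei.

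Without core genes higher in empty droplets the ratio was 1.66, 2.10 and 1.199 over all neurons, 3.20 for LH and 3.81 for NAc in dopaminergic-like nuclei, and 1.55 for NAc and 1.22 for PFC in glutamatergic-like nuclei. The median over list members was 1.72, 2.58 and 1.21 over all neurons, 4.87, 9.47 and 1.62 in dopaminergic-like nuclei, and 1.14 for LH and 1.68 for NAc in glutamatergic-like nuclei. With the extended list the ratio was 1.53 for LH and 1.91 for NAc over all neurons, 2.11, 3.22 and 1.12 in dopaminergic-like nuclei, 1.61 for NAc in glutamatergic-like and 1.31 for NAc in GABAergic-like nuclei. Without the most abundant core gene it was 3.20, 6.08 and 1.77 in dopaminergic-like nuclei. With clusters weighted equally it was 1.63 for LH and 2.57 for NAc over all neurons, 3.08 for LH in dopaminergic-like nuclei, and 1.12 for LH and 1.25 for PFC in glutamatergic-like nuclei.

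With neuronal clusters named by transmitter genes alone, which by construction adds cluster 5 to the glutamatergic-like class, that class had 1.10 for LH and 1.70 for NAc. With Leiden resolution 2.0 the dopaminergic-like ratio for NAc was 8.05 and the glutamatergic-and-GABAergic-like one for LH 6.06. With a mitochondrial limit of 1% the latter class had 6.74 for LH, 4.80 for NAc and 2.61 for PFC. In glutamatergic-like nuclei the ratio was 1.10 for LH and 1.73 for NAc with a UMI threshold per library, 1.10 and 1.71 with activity genes kept for clustering, and 1.09, 1.71 and 1.27 without doublet removal. Without doublet removal microglia-like nuclei were 24.5% of named nuclei for LH, 20.8% for NAc and 38.5% for PFC, against 25.9%, 24.1% and 39.7% of named nuclei with it. The cause was not tested in these settings.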

Other observations

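No test was chosen here, and the genes named were chosen after their values were seen.

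In barcodes without a nucleus the dopamine neuron transcripts Slc6a3 and Th were more abundant than over all neurons. Slc6a3 was 541 CPM in empty barcodes of the control, 528 with the LH input, 355 with the NAc input and 365 with the PFC input, against 160.5, 137, 133 and 121 CPM over all neurons. In dopaminergic-like nuclei Slc6a3 was 489, 495, 598 and 421 CPM, above the empty barcodes with the NAc and PFC inputs only. Th was 277, 165, 99.8 and 70.9 CPM in empty barcodes and 64.2, 51.0, 44.0 and 27.2 CPM over all neurons.

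Haemoglobin transcripts, a mark of blood, were most abundant with the NAc input. Hbb-bs was 62.7 CPM in empty barcodes of the control, 149 with the LH input, 1667 with the NAc input and 107 with the PFC input, and an unnamed cluster led by haemoglobin genes held 67, 403, 556 and 234 nuclei. The pituitary hormone genes Prl and Gh were 201 and 51.7 CPM in empty barcodes of the control and 0 in those of the other 3 libraries. Malat1, a nuclear long non-coding RNA, was 31796 CPM in control neurons and 23461, 23507 and 20015 CPM in the others.

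The X-inactivation transcript Xist was 318 CPM over all nuclei of the control pool, 275 with the LH input, 637 with the NAc input and 781 with the PFC input. The Y-linked gene Uty was 109.6, 127, 57.8 and 53.9 CPM, and the Y-linked gene Ddx3y 37.0, 56.0, 26.7 and 26.7 CPM. Over all neurons Xist was 250, 203, 425 and 326 CPM and Uty 108, 108, 36.7 and 69.3 CPM. The mix of sexes in the pools was not used here. It cannot be told apart from the input in the NAc and PFC comparisons.

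In microglia-like nuclei the homeostatic marker Siglech was 771 CPM in the control against 145, 173 and 152 CPM with the LH, NAc and PFC inputs, and P2ry12 816 against 289, 294 and 272 CPM. The control had 97 such nuclei, of which 85 lay in cluster 4, led by Siglech, while the other libraries had most of theirs in other microglia-like clusters. A cluster of 711 newly formed oligodendrocyte-like nuclei had 8 from the control, and cluster 9 of oligodendrocyte precursor-like nuclei had 1 of 1163.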
